A study of Homo sapiens with 21 samples.

How the data were processed

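Total RNA from pooled human neural stem and progenitor cells and from the LN229 glioblastoma line was compared on 21 Agilent whole human genome arrays read in Cy5 and Cy3, in 4 groups: unamplified RNA (5 arrays) and RNA amplified from 20 ng (5), 1 ng (5) and 20 pg (6) of input. Per the labels, 10 µg of RNA was labelled for an array and all arrays of a group were technical replicates. Mean spot and median local background signals were intensity values in scanner units per the file headers, without normalization. Processed signals were also intensity values, from which Feature Extraction had subtracted the background and normalized the dyes, per the file headers. The deposited ratio column held log10 values of Cy5 over Cy3. Other deposited columns held 0 or 1 flags per spot for signals well above background, positive and significant signals, saturation and outlier spots, which per the file headers have a unit of their own kind. The submitters' processing notes name Agilent Feature Extraction 9.5. The submitters' series matrix, checked against the spot files, held log2 values of progenitor over LN229, dye-swapped arrays included, with the median of a column ranging from -0.237 to 0.299. Array headers named 2 scanner models with a Feature Extraction version each (9.5.1.1 earlier and 10.1.1.1 later) and 6 slides, and the scan batches (8 earlier and 13 later arrays, each with all 4 groups) were taken from them.

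Signals were corrected in limma 3.58.1 (R 4.3.3) with normexp and an offset of 50, and outlier spots were left out. Log2 ratios were normalized by loess within arrays, and spots of a probe were averaged. Probes were named by current symbols through their sequence records or older symbols. A gene was represented by its probe with the highest average intensity over all arrays. Genes were tested if their probe was well above background in at least 1 channel on at least 4 arrays of at least 1 group, which left 22051 genes. The 74 probes of genes that could show personal traits were left out before any test. One limma model of all 21 arrays held a coefficient per group, turned in sign for dye-swapped arrays, and a gene-wise dye term, with array weights from 1 variance factor per group. A call needed a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 value of at least 1, and all tests were two-sided. Average intensities were quantile normalized and compared in the same way without the dye term. Detection and array deviations were compared by exact permutation tests, and adjusted over the tests of a measure, and exchanges within scan batches only were added after the data had been seen. Where an RNA stood below background on every array, its level was taken as the higher of its own level and the lowest level of any spot well above background on that array, which gave a lower bound of the fold. For 25 gene lists camera tested ratios and intensities against all other genes with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and the tests were repeated with an estimated correlation and with fry. The lists held neural stem and progenitor, neuronal, astroglial, oligodendrocyte lineage, mesenchymal and adhesion, inflammatory, interferon and MHC class I, proliferation, Notch, Wnt and hedgehog, pluripotency, microglia and macrophage, endothelial, fibroblast and mural cell and erythroid genes. Others held widely expressed reference, ribosomal protein, mitochondrial genome, respiratory chain, replication-dependent histone, HOX, cancer-testis, metallothionein, proteasome and collagen genes and small nucleolar RNAs.

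Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 10 highest and 10 lowest unamplified ratios among called genes above background in both channels with the same sign on all arrays, and the 3 highest and 3 lowest lower bounds. It also named, for each amplified group, the 8 highest and 8 lowest ratio differences with non-overlapping arrays and the 6 highest and 6 lowest intensity differences, and up to 4 called members of each list with the largest absolute value. SOX2, NES, DCX, OLIG2, GFAP, VIM, CD44, FN1, MYC, EGFR, CDKN2A, ACTB and GAPDH were always named if tested, and DCX did not pass the filter. A few genes that the rule picks were left out of the text. Alternatives were the processed signals or series matrix values, an offset of 1, median centring or scale normalization, no filter or a strict one and all spots kept. Others were no dye term or dye-swapped arrays left out, equal weights, a replicate block, slides as blocks, the mean of a gene's probes, no fold minimum, only the groups compared, another detection flag and each array left out in turn. A dye term per group, either scan batch alone, the batch as a block for intensities and lists and a fit without the later 1 ng and 20 pg arrays were added after the data had been seen. The procedure was tested on simulated data with known differences. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Signal over background and the number of arrays limit the precision.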

Results

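Gene expression was measured on 21 oligonucleotide arrays that each carried 41000 gene probes and were read in 2 colours. Every array compared RNA from pooled human neural stem and progenitor cells, which can give rise to neurons and glia, with RNA from LN229, an established human glioblastoma cell line. Unamplified RNA was hybridised on 5 arrays, and RNA amplified from 20 ng, 1 ng and 20 pg of input on 5, 5 and 6 arrays. The comparisons address how far the ratios of progenitor over LN229 RNA measured after amplification follow those of unamplified RNA. The progenitor RNA carried Cy3 in place of Cy5 on 1 array of each of the unamplified, 20 ng and 1 ng groups and on 2 arrays of the 20 pg group. Replicates 1 and 2 of every group, 8 arrays, none dye-swapped, came from an earlier scanner model and the other 13 from a later one. Earlier-batch fits thus keep any dye bias. The batches also differed in the Feature Extraction version, from which the detection flags come. All arrays of a group were named technical replicates. It is not stated whether the amplification was repeated for each array, so the p-values may cover hybridisation error only.

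Fewer gene probes rose above background after amplification from 20 ng. In the progenitor channel 71.3% ± 9.15 of probes (SD, n = 5) stood well above background in unamplified RNA and 47.2% ± 11.4 (SD, n = 5) in the 20 ng group. In the LN229 channel the shares were 69.8% ± 10.3 and 46.4% ± 8.79 (SD, n = 5 each). Both differences passed a two-sided exact permutation test of the 5 against 5 arrays (p = 0.00794 in each channel, adjusted p = 0.0238 over 6 tests, with no overlap between the groups, and adjusted p = 0.0229 when arrays were exchanged within scan batches only). The 1 ng group reached 42.5% ± 37.4 in the progenitor and 38.3% ± 31.4 in the LN229 channel (SD, n = 5), with exact adjusted p = 0.167 and 0.114 against unamplified RNA, and 0.100 and 0.0229 within scan batches. For the 20 pg group the shares were 38.4% ± 36.2 and 32.2% ± 20.3 (SD, n = 6), with exact adjusted p = 0.110 and 0.0303, and 0.0229 in both channels within scan batches. The wide spread of these 2 groups followed the scan batch. In the progenitor channel the unamplified, 20 ng, 1 ng and 20 pg arrays averaged 81.1%, 52.5%, 82.9% and 84.7% in the earlier and 64.7%, 43.6%, 15.5% and 15.2% in the later batch. Averaged over both channels, 70.5% of probes were detected in unamplified RNA and 46.8%, 40.4% and 35.3% after amplification from 20 ng, 1 ng and 20 pg, but 79.3%, 53.4%, 77.3% and 71.0% in the earlier batch, so the decline from 20 ng to 20 pg came from the later batch.

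**Figure D1:**
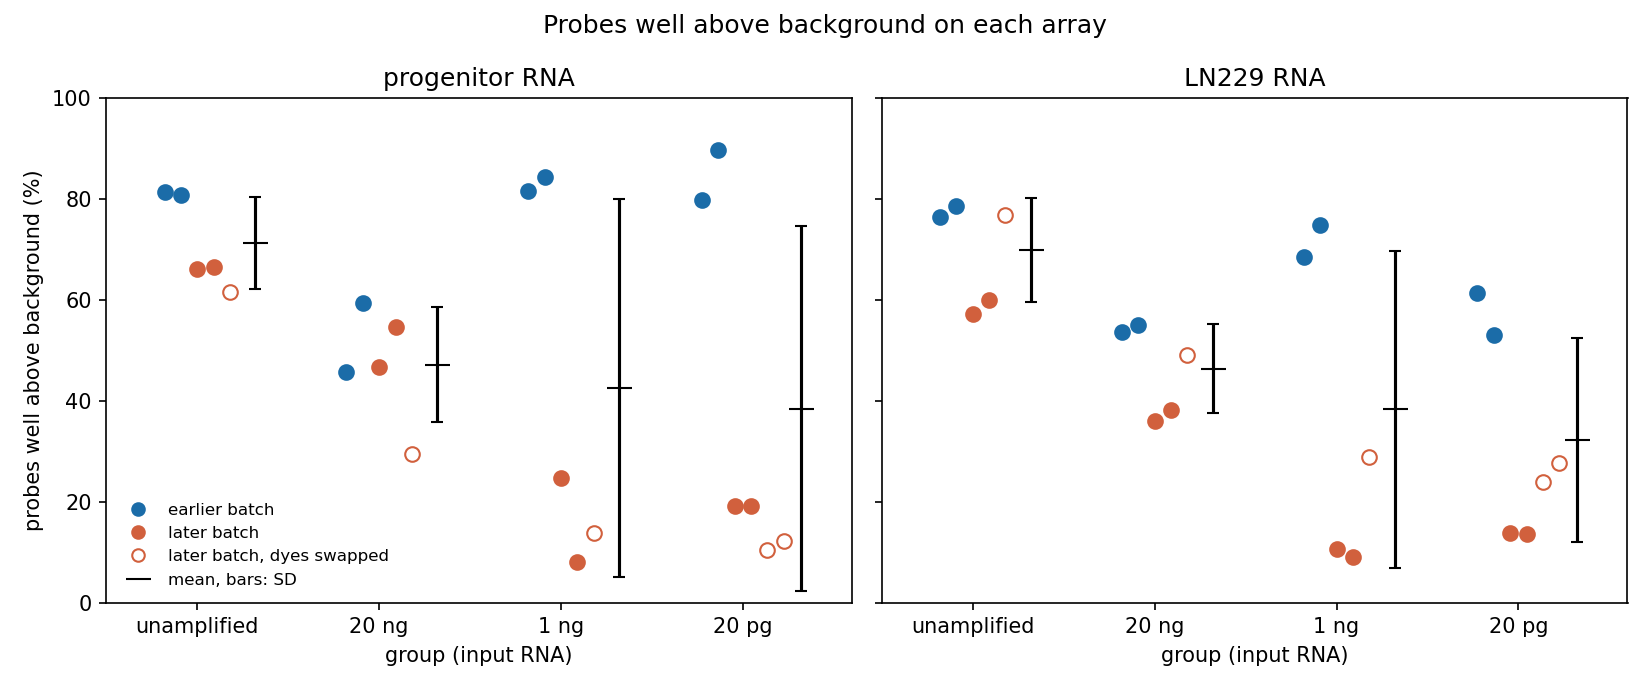
Percent of gene probes well above background on each array, by group, for the progenitor and the LN229 channel.

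The unamplified arrays show which genes differed between the progenitor cells and the glioblastoma line. COL3A1 and COL1A2, which encode fibrillar collagen chains, were higher in the progenitor RNA, with log2 ratios of 6.44 ± 0.57 and 6.12 ± 0.91 (SD, n = 5). PLAU, the urokinase-type plasminogen activator, reached 6.27 ± 0.45, COL5A2, another fibrillar collagen chain, 5.07 ± 0.36, and ISG15, an interferon-induced ubiquitin-like protein, 5.04 ± 1.15 (SD, n = 5). The DNA helicase HELB had a log2 ratio of 5.23, HAAO, an enzyme of tryptophan breakdown, 5.21, RASAL3 5.05, SERINC2 5.04 and the receptor GPR32 5.02. Genes higher in the LN229 RNA included CD74, the invariant chain of MHC class II, at a log2 ratio of -5.82 ± 0.38, and the class II chains HLA-DRA at -5.23 ± 0.69, HLA-DPA1 at -5.05 ± 0.41 and HLA-DRB5 at -4.97 ± 0.49 (SD, n = 5). MPHOSPH9 stood at -5.80, the growth factor PGF at -5.76, the pseudogene OVOS2P at -5.29, MIA, a secreted protein of melanoma and cartilage cells, at -5.23, the retinaldehyde dehydrogenase ALDH1A3 at -5.07 and GAS7 at -4.75. Each of these 20 genes kept its sign on 5 of 5 arrays, as the rule required, and the highest adjusted p among them was 3.03e-07. COL3A1 lies on chromosome 2, COL1A2 on chromosome 7, PLAU on chromosome 10, CD74 on chromosome 5 and MIA on chromosome 19, with no genome build or exon positions in the annotation. For genes below background on every array in 1 of the RNAs only a lower bound was available, open to dye bias because few arrays were swapped: the Ras-like GTPase gene DIRAS3, LRRN1 and the fucosidase gene FUCA2 were at least 24.3-, 18.7- and 15.8-fold higher in the progenitor RNA.

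Among genes chosen beforehand, the progenitor factor SOX2 was lower in the progenitor than in the LN229 RNA, at a log2 ratio of -2.07 ± 0.25 (SD, n = 5, adjusted p = 7.39e-06, lower on 5 of 5 arrays). NES, an intermediate filament of neural progenitors, stood at -0.82 (adjusted p = 0.000134, higher in the progenitor RNA on 0 of 5 arrays) and OLIG2, a factor of the oligodendrocyte lineage, at -0.83 (adjusted p = 2.62e-05, 0 of 5), both short of the 2-fold minimum. OLIG2 was called at -2.35 with the processed signals, -2.38 with the series matrix values, -1.35 with an offset of 1 and -1.10 in the later batch. The fibronectin gene FN1 reached 2.64 ± 0.07 and CDKN2A, which encodes the cell cycle inhibitor p16, 4.39 ± 0.34 (SD, n = 5), both higher in the progenitor RNA on 5 of 5 arrays (adjusted p = 3.11e-12 and 1.12e-10). The receptor gene EGFR stood at 1.54 (adjusted p = 8.11e-10, 5 of 5 arrays) and the intermediate filament gene VIM at 1.05 (adjusted p = 3.98e-05, 5 of 5). VIM fell short of the 2-fold minimum under 10 alternatives, lowest at 0.71 with a dye term per group and the scan batch as a block. GFAP, the astrocyte filament, at 0.48 (adjusted p = 0.00999, 5 of 5), CD44 at 0.55 (adjusted p = 0.00269, 5 of 5), MYC at -0.34 (adjusted p = 0.107, 0 of 5), ACTB at 0.22 (adjusted p = 0.134, 4 of 5) and GAPDH at -0.08 (adjusted p = 0.611, 2 of 5) were not called. In all, limma called 3413 of 22051 genes, 1859 higher in the progenitor and 1554 higher in the LN229 RNA. The count was 3668 with the scan batch as a block, 4512 in the earlier batch and 3548 in the later batch, 5719 with the processed signals and 5765 with the series matrix values. In simulated data the test recovered 99% of genes changed by a log2 ratio of 1.5 and 100% of those changed by 3.

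Histone and proliferation genes were higher in the LN229 RNA. Of 64 replication-dependent histone genes, 59 were called lower in the progenitor RNA, 1 higher and 4 neither, with a median log2 ratio of -2.75, and H2AC19 at -3.34, H3C2 at -3.30 and H2BC11 at -3.20. All 20 proliferation genes were called lower (median -2.30), among them RRM2, a ribonucleotide reductase subunit, at -3.73, the replication clamp PCNA at -2.80 and the topoisomerase TOP2A at -2.75. Cancer-testis antigen genes, which most adult tissues keep silent, were called lower for 14 and higher for 1 of 29, with MAGEA12 at -4.12 and MAGEA1 at -3.94. Of 11 oligodendrocyte lineage genes 5 were called lower, 0 higher and 6 neither, with the lineage factor SOX10 at -4.27 and NKX2-2 at -1.68. In the other direction 10 of 12 fibroblast and mural cell markers were called higher in the progenitor RNA and 0 lower (median 3.54), including POSTN at 5.28 and the smooth muscle actin gene ACTA2 at 4.96. Mesenchymal and adhesion genes were called higher for 14 of 24 and lower for 0 (median 1.27), with CHI3L1 at 4.16. Collagen genes were called higher for 16 and lower for 5 of 39, with COL14A1 at 4.93, and interferon and MHC class I genes higher for 6 and lower for 0 of 18, with HLA-B at 1.23, a call that ended with the mean of its probes (0.96) and in the later batch alone (0.88). Called members numbered the same when adjusted over the list alone.

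Set against all other genes, 8 lists were called by camera, none of them with an inter-gene correlation estimated per list. The histone list fell with adjusted p = 4.62e-68, the proliferation list with 3.8e-19, the cancer-testis list with 6.07e-06 and the oligodendrocyte list with 0.00594. The fibroblast list rose with adjusted p = 1.51e-12, the mesenchymal list with 8.16e-16, the collagen list with 7.07e-05 and the interferon list with 0.0221. With the preset correlation 10 lists had an unadjusted p under 0.05, and fry, a rotation test of the list alone, called 18. The adjusted p with an estimated correlation was 0.0953 for the fibroblast list, 0.140 for the interferon list and 0.127 for each of the other 6. All 8 directions were the same in both scan batches and with the batch as a block, although the interferon list had adjusted p = 0.0626 in the later batch.

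The remaining 17 lists did not pass the test in unamplified RNA, although members of several differed. Of 15 neural stem and progenitor genes 6 were called higher and 3 lower (adjusted p = 0.0764), with the cerebellar and dorsal neural factor ZIC1 at 4.36, PAX6 at 2.58 and the radial glia fatty acid binding protein FABP7 at -3.27. Neuronal genes were called higher for 5 and lower for 1 of 18 (adjusted p = 0.512), including the neurofilament genes NEFM at 2.92 and NEFL at 1.53. Astroglial genes split, with 2 called higher and 3 lower of 10 (adjusted p = 0.353): the glutamate transporter SLC1A3 stood at 3.22 and the gap junction gene GJA1 at 3.14, S100B at -4.41 and PTPRZ1 at -3.49. HOX genes were called higher for 5 and lower for 9 of 32 (adjusted p = 0.129), with HOXB2 at 3.42 and HOXC10 at -2.44, and Notch, Wnt and hedgehog genes higher for 2 and lower for 6 of 19 (adjusted p = 0.121), with HHIP at 2.81 and LEF1 at -3.01. Inflammatory genes were called higher for 1 and lower for 2 of 15 (adjusted p = 0.660), with the chemokine gene CCL2 at 2.60 and CXCL1 at -1.40. Proteasome genes were called higher for 3 and lower for 3 of 37 (adjusted p = 0.332), ribosomal protein genes higher for 5 and lower for 0 of 84 (0.285), respiratory chain genes higher for 2 and lower for 0 of 77 (0.382) and metallothionein genes higher for 2 and lower for 0 of 11 (0.454). Transcripts of the mitochondrial genome were called higher for 2 and lower for 0 of 6 (adjusted p = 0.0764), endothelial genes for 2 and 0 of 6 (0.129), and widely expressed reference genes for 1 and 3 of 16 (0.207), where the median of -0.07 turned positive relative to all genes with median centring in place of loess. Of 8 microglia and macrophage genes 0 were called higher and 0 lower, of 8 erythroid genes 0 and 0, of 4 pluripotency genes 0 and 0, and of 4 small nucleolar RNAs 0 and 0 (adjusted p = 0.660, 0.939, 0.660 and 0.936).

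Amplification from 20 ng was compared with unamplified RNA to see which ratios changed. COL1A2 stood at a log2 ratio of 6.57 ± 0.48, PLAU at 6.18 ± 0.16, CD74 at -5.40 ± 0.27 and MIA at -5.85 ± 0.22 after amplification (SD, n = 5), while HELB stood at 1.63 and COL5A2 at 2.83. Among named genes whose arrays did not overlap, the largest loss was in ASCL2, a basic helix-loop-helix transcription factor, which fell from 4.33 to 0.75 (difference -3.57 ± 0.65, SE, adjusted p = 0.000666). CITED2, a transcriptional co-regulator, fell from 3.30 to 0.39 (difference -2.91 ± 0.24, SE, adjusted p = 1.81e-07), and FAU, which encodes a ribosomal protein fused to a ubiquitin-like domain, from 1.91 to -0.88. PPP2R5D, HLA-DRB3, PLEKHJ1, the protocadherin gene PCDHA5 and FSCN2 differed by -3.12, -3.05, -2.91, -2.84 and -2.76. The largest gains among them were in the cyclin gene CCNF, from -1.88 to 0.28 (difference 2.17 ± 0.23, SE, adjusted p = 3.05e-06), and the smooth muscle gene TAGLN, from 3.70 to 5.84 (difference 2.13 ± 0.54, SE, adjusted p = 0.0105). CAPS, GNG2, the kinetochore gene KNL1, the hexokinase HK3, CADM3 and the mesenchymal factor TWIST1 gained 2.09, 2.07, 1.97, 1.94, 1.86 and 1.83. For each of these 16 genes the 5 amplified arrays did not overlap the 5 unamplified ones, as the rule required. With the mean of all probes of a gene, the calls of CAPS, GNG2 and HK3 ended, those of TAGLN and CADM3 with equal array weights (that of TAGLN also with median centring), and those of TAGLN, PPP2R5D and FAU with the slide as a fixed block.

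Of the 3413 genes called in unamplified RNA, 1592 were called the same way from 20 ng, which is 46.6%. Of the others 1820 were not called and 1 was called the opposite way. That gene, HAGHL, chosen after its values were seen, had log2 ratios of 1.16 and -1.07, and its unamplified call ended under 7 alternatives (0.22 in the earlier batch alone). In the 20 ng group 1894 genes were called, 855 higher in the progenitor and 1039 higher in the LN229 RNA, against 4424 with the processed signals, 4497 with the series matrix values, 3024 with an offset of 1 and 3793 in the earlier batch. The ratio differed from the unamplified one for 1014 genes, 371 upward and 643 downward. Of those called in unamplified RNA 846 shifted toward 0 and 9 away, and 159 were not called there. Selection on the same arrays favours shifts toward 0, at 1 ng and 20 pg too. With the scan batch as a block 1149 genes differed, with 1981 in the earlier and 1112 in the later batch, and the scale normalization between arrays gave 634. Simulated recovery was 98% at 1.5 and 99% at 3.

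Of the 8 lists that camera called before amplification, all but the oligodendrocyte lineage (adjusted p = 0.151, 4 of 11 called lower) were called from 20 ng as well, but with an estimated correlation 0 of 8 calls held before and 1 of 11 after it. Histone genes were called lower in the progenitor RNA for 59 and higher for 1 of 64 (median -2.48), with H2BC21 at -3.10, and all 20 proliferation genes were called lower (median -1.86), with RRM2 at -3.26 and the thymidylate synthase TYMS at -2.45. Fibroblast and mural cell markers were called higher for 10 and lower for 0 of 12 (median 3.66), with TAGLN at 5.84 and COL1A1 at 4.00. Mesenchymal genes were called higher for 14 and lower for 0 of 24 (median 1.44), with TGFBI at 3.52. Cancer-testis genes were called lower for 11 of 29, with MAGEA1 at -3.76, collagen genes higher for 12 and lower for 2 of 39, with COL9A3 at -3.04, and interferon genes higher for 4 of 18. Camera gave adjusted p = 4.67e-108 for the histone list, 1.02e-25 for the mesenchymal, 4.78e-25 for the proliferation, 5.71e-21 for the fibroblast, 1.64e-07 for the cancer-testis, 1.37e-05 for the collagen and 0.00698 for the interferon list. Of these, the fibroblast call held (adjusted p = 0.0243 with an estimated correlation), and the others reached 0.0676, 0.0676, 0.0676, 0.0893, 0.0893 and 0.140 in the same order. Lists called here and not in unamplified RNA were the ribosomal protein and mitochondrial genome lists, upward (adjusted p = 0.0248 and 0.0274), and the proteasome and Notch, Wnt and hedgehog lists, downward (0.0248 and 0.0365). They had adjusted p = 0.603, 0.0893, 0.550 and 0.140 with an estimated correlation. The ribosomal list turned downward in the earlier batch (adjusted p = 0.928), its call and the Notch call ended with the scan batch as a block (0.0944 and 0.102). The proteasome and mitochondrial genome calls ended in the later batch (0.342 and 0.115). Counts of called members were the same when adjusted over the list alone. In the difference from unamplified RNA camera called 0 of 25 lists, 5 had an unadjusted p under 0.05, and fry called 3. The lowest adjusted p was 0.0671, for the oligodendrocyte list, where the SOX10 ratio moved from -4.27 to -1.25, a call that ended with the processed signals.

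From 1 ng most of the ratios that differed from unamplified RNA had shifted toward 0. COL1A2 stood at a log2 ratio of 5.23 ± 2.04, PLAU at 5.10 ± 2.05, CD74 at -3.19 ± 1.95 and MIA at -4.22 ± 1.54 (SD, n = 5). IGFBP4, which binds insulin-like growth factors, fell from 4.42 to 1.35 (difference -3.07 ± 0.28, SE, adjusted p = 6.13e-07), the matrix gene LTBP2 from 4.89 to 1.89 and ASCL2 from 4.33 to 0.59. CITED2, the cytochrome CYP2W1, PCDHA5 and MEF2B differed by -3.17, -2.84, -2.82 and -2.59. CADM3, a cell adhesion gene, moved from -3.28 to -0.19 (difference 3.09 ± 0.42, SE, adjusted p = 4.86e-05), CAPS moved from -3.62 to -1.22, and the mitotic spindle gene PSRC1 from -1.53 to 0.00 (difference 1.52 ± 0.16, SE, adjusted p = 1.99e-06). NOL4L, HMG20B, FOXD2 and the histone variant gene H2AJ gained 2.23, 1.57, 1.47 and 1.52. The amplified arrays of these 14 genes did not overlap the unamplified ones, as the rule required. SPEF1 had the highest difference among genes whose arrays did not overlap (3.14 ± 0.97, SE, adjusted p = 0.0356), and its call ended without any single 1 ng array or without unamplified replicate 3, 4 or 5. The SPEF1 difference was then 2.44 to 3.17, with adjusted p from 0.0529 to 0.107. H2AJ reversed to -0.55 as the mean of its probes, and HMG20B, FOXD2, LTBP2 and SPEF1 lost their calls in the earlier batch alone. The calls of LTBP2, ASCL2, PCDHA5, MEF2B, NOL4L, HMG20B, FOXD2, H2AJ and SPEF1 ended under at least 1 alternative. Without the later 1 ng and 20 pg arrays the 1 ng calls of ASCL2 (-2.69), PCDHA5 (-2.01) and MEF2B (-1.10) ended as well.

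In the 1 ng group 568 genes were called, 228 higher and 340 lower in the progenitor RNA (42 with only the 1 ng arrays in the fit, 9 higher and 33 lower), and 513 of the 3413 unamplified calls, 15.0%, were called the same way with 0 opposite. With each array left out these were 285 to 955 genes and 7.34% to 24.2%. The ratio differed from the unamplified one for 1502 genes, 578 upward and 924 downward. Of those called, and so selected, in unamplified RNA 1334 shifted toward 0 and 0 away, and 168 were not called there. The number called in the 1 ng group varied with the scan batch, at 4916 in the earlier and 275 in the later batch and 1111 with the batch as a block, and the number that differed was 1952, 2891 and 1698. Called were 1359 with the processed signals, 1258 with the series matrix values and 1174 with an offset of 1. Simulated recovery was 81% at 1.5 and 99% at 3.

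At 1 ng the histone genes called lower in the progenitor RNA numbered 51 of 64 (53 adjusted over the list alone, median -1.83), with H2BC15 at -2.70. Fibroblast markers called higher numbered 7 of 12 (8 adjusted over the list alone, median 2.10), with TAGLN at 4.66. Mesenchymal genes were called higher for 11 of 24 (12 adjusted over the list alone), with TGFBI at 2.93, and proliferation genes lower for 7 of 20 (12 adjusted over the list alone), with the cyclin gene CCNB1 at -1.96. Camera called these 4 lists with adjusted p = 2.55e-108, 2.69e-16, 4.26e-26 and 5.96e-15, and the adjusted p was 0.0245, 0.0193, 0.0310 and 0.0824 with an estimated correlation. The collagen (4 called higher and 1 lower of 39, and 6 and 1 adjusted over the list alone), interferon and mitochondrial genome lists were called upward (adjusted p = 2.39e-05, 0.000819 and 0.0112). Camera called the cancer-testis (3 of 29 called lower, 8 adjusted over the list alone), metallothionein and proteasome lists downward (0.000844, 0.00807 and 0.0153). None of the 6 calls held with an estimated correlation (adjusted p = 0.0682, 0.0682, 0.0682, 0.267, 0.561 and 0.669). The ribosomal protein list, up with adjusted p = 0.0157 (0.669 with an estimated correlation), turned downward with median centring in place of loess and lost its call with the scan batch as a block (adjusted p = 0.170). Relative to unamplified RNA camera called 7 lists, none of them with an estimated correlation. The histone list shifted upward, toward 0, with 11 of 64 called higher and 1 lower (17 and 1 adjusted over the list alone, median 0.81), and the proliferation list with 9 of 20 called higher (11 adjusted over the list alone, median 1.20). H2AC4 moved from -2.53 to -1.09, a change that ended in the earlier batch alone. The fibroblast list shifted downward, 6 of 12 called lower (7 adjusted over the list alone, median -1.27), as did the mesenchymal list, 5 of 24 (median -0.52), and the collagen list, 6 of 39 called lower and 2 higher (median -0.21). Called higher were 3 of 11 oligodendrocyte (list median 0.37) and 4 of 29 cancer-testis genes (6 adjusted over the list alone, median 0.44). The adjusted p were 2.11e-12, 1.06e-09, 0.00138, 0.00382, 0.0449, 0.00342 and 0.00117 in this order and, with an estimated correlation, 0.458, 0.347, 0.347, 0.562, 0.458, 0.347 and 0.383. In this comparison 9 lists had an unadjusted camera p under 0.05 and fry called 11. Within batches the histone median was 0.20 in the earlier batch (adjusted p = 0.0108) and 1.13 in the later, the proliferation median -0.18 (0.894) and 1.92, the fibroblast median -0.15 (0.669) and -1.93, the mesenchymal median 0.01 (0.586) and -0.88, the collagen median -0.06 (0.869) and -0.73, the oligodendrocyte median 0.17 (0.648) and 0.78 and the cancer-testis median -0.13 (0.648) and 1.07.

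From 20 pg, ratios lay close to 0 for many genes called in unamplified RNA, whose median absolute log2 ratio fell to 0.252. PLAU stood at a log2 ratio of 5.25 ± 0.65, MIA at -5.20 ± 1.55, HLA-DRA at -4.25 ± 1.37 and COL1A2 at 4.39 ± 0.53 (SD, n = 6). HAAO fell from 5.21 to 0.12 (difference -5.09 ± 0.87, SE, adjusted p = 0.000451) and LTBP2 from 4.89 to 0.41. The transcription factor subunit gene GTF3C5 differed by -4.61 ± 0.43 (SE, adjusted p = 5.43e-07), and ASCL2, GPR32, FAM83E and PCDHA5 by -4.64, -4.27, -3.95 and -3.93. On the other side CAPS rose from -3.62 to -0.45 (difference 3.17 ± 0.49, SE, adjusted p = 0.000165) and BIRC5, the survivin gene of dividing cells, from -3.04 to -1.13 (difference 1.91 ± 0.46, SE, adjusted p = 0.00596). The ceramide transporter CERT1, the kinase FAM20C, FOXD2, H2AJ and PSRC1 gained 2.58, 2.02, 1.94, 1.88 and 1.77, and SPEM2 gained 1.77, or 0.93 and no longer called without 20 pg replicate 2. No amplified array overlapped the unamplified ones for any of these 15 genes, as the rule required. In the earlier batch alone the calls of BIRC5, CERT1, FAM20C, FOXD2, H2AJ, PSRC1 and SPEM2 ended, and H2AJ reversed to -0.69 as the mean of its probes. BIRC5, CERT1, FAM20C, FOXD2, H2AJ, PAX6 and SPEM2 also lost their calls under other alternatives. PAX6 moved from 2.58 to 0.44 and the RNA-binding progenitor gene MSI1 by -1.63, and both calls ended in the earlier batch as well. Without the later 1 ng and 20 pg arrays the 20 pg differences of HAAO, ASCL2, GPR32, FAM83E and PCDHA5 were -5.67, -5.50, -3.72, -4.42 and -4.95 and no longer called.

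At 20 pg 584 genes were called, 88 higher and 496 lower in the progenitor RNA (earlier batch 32 and 548, later 155 and 326). With only 20 pg arrays in the fit 61 were called, 27 higher and 34 lower. Earlier LN229 channels had 57.2% of probes detected, progenitor channels 84.7%. Of the 3413 unamplified calls 306, 8.97%, were called the same way and 0 the opposite way, and 74.5% had the same sign, against 96.5% from 20 ng and 94.5% from 1 ng. The ratio differed from the unamplified one for 2569 genes, 883 upward and 1686 downward. Of those called, and so selected, in unamplified RNA 2019 shifted toward 0 and 7 away, and 543 were not called there. With the scan batch as a block 891 genes were called and 2773 differed, with 580 and 535 in the earlier and 481 and 2939 in the later batch. Simulated recovery was 74% at 1.5 and 96% at 3.

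At 20 pg 37 of 64 histone genes were called lower in the progenitor RNA (47 adjusted over the list alone, median -1.36), with H4C2 at -3.14 and H4C3 at -2.96. Proteasome genes were called lower for 8 of 37 (9 adjusted over the list alone, median -0.65), with PSMA2 at -2.01, and respiratory chain genes lower for 12 and higher for 1 of 77 (median -0.40), with NDUFS6 at -1.61. Fibroblast markers were called higher for 4 of 12 (6 adjusted over the list alone), with TAGLN at 4.62, mesenchymal genes for 6 of 24, with TGFBI at 3.55, and proliferation genes lower for 2 of 20 (5 adjusted over the list alone), with CCNB1 at -1.37. Camera gave adjusted p = 1.23e-68, 5.4e-10, 3.84e-09, 5.4e-10, 8.47e-14 and 7.93e-05, and adjusted p = 0.0691, 0.160, 0.160, 0.0691, 0.160 and 0.388 with an estimated correlation. The metallothionein list fell (median -0.70, adjusted p = 2.16e-07, or 0.160 with an estimated correlation) and the collagen list rose (median 0.06, adjusted p = 0.00840, or 0.288 with an estimated correlation).

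Against unamplified RNA 10 lists were called by camera, none of them with an estimated correlation. The histone list shifted upward, 31 of 64 called higher and 1 lower (36 and 1 adjusted over the list alone, median 1.07), with H2AC4 from -2.53 to -0.57, a call that ended in the earlier batch alone. Of 20 proliferation genes 13 were called higher (16 adjusted over the list alone, median 1.72), with PCNA from -2.80 to -0.95 (ended in the earlier batch alone), of 29 cancer-testis genes 9, and of HOX genes 10 higher and 3 lower of 32. Called lower were 5 of 12 fibroblast markers (8 adjusted over the list alone, median -1.78), 8 of 24 mesenchymal genes and 7 of 39 collagen genes, with 1 higher (9 and 1 adjusted over the list alone). Of 37 proteasome genes 6 were called lower, PSMC4 by -2.61, a call that ended with the strict filter, with the slide as a fixed block and without the later 1 ng and 20 pg arrays. The respiratory chain list shifted downward (median -0.34) with 3 of 77 called lower, and 3 of 11 oligodendrocyte genes were called higher (4 adjusted over the list alone). Counts given once were the same when adjusted over the list alone. The adjusted p were 2.67e-15 for histone, 3.46e-12 for proliferation, 6.9e-05 for cancer-testis, 0.0198 for HOX, 0.000378 for fibroblast, 0.000130 for mesenchymal, 0.0164 for collagen, 0.0284 for oligodendrocyte and 0.0339 for proteasome and for respiratory chain genes. With an estimated correlation they were 0.345, 0.294, 0.294, 0.188, 0.294, 0.465, 0.345, 0.345 and 0.624 in that order, the last for both proteasome and respiratory chain genes. The histone median was 0.05 in the earlier (adjusted p = 0.424) and 1.78 in the later batch. The proteasome median was -1.01 in the earlier and -0.11 in the later batch (adjusted p = 0.742). The cancer-testis, collagen, HOX and oligodendrocyte calls ended in the earlier batch (adjusted p = 0.137, 0.0518, 0.0518 and 0.726) and the HOX and respiratory chain calls in the later (0.159 and 0.742).

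**Figure D2:**
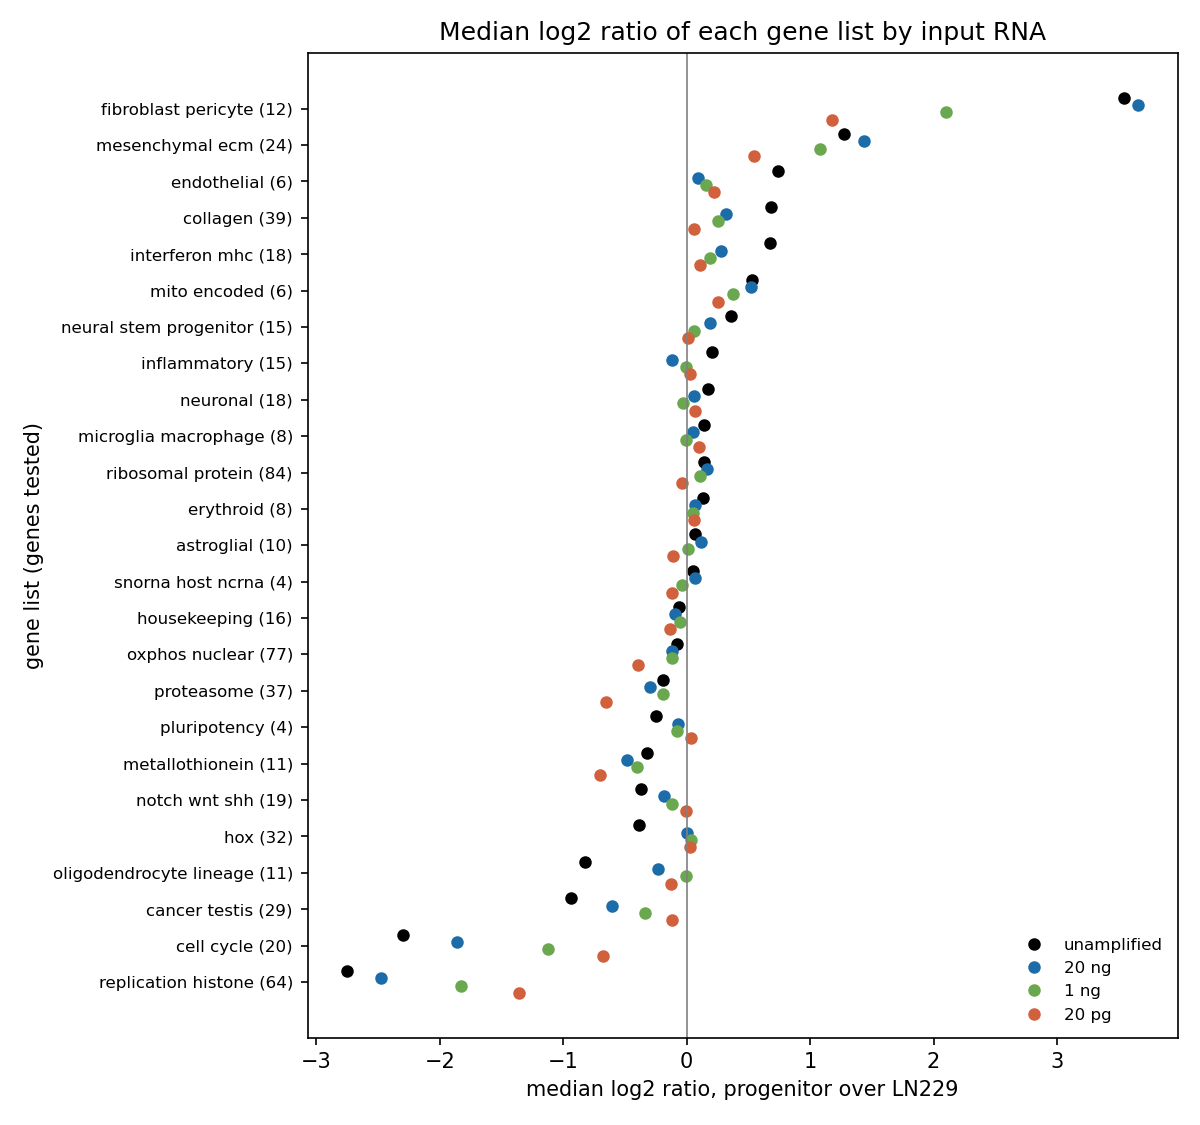
Median log2 ratio of progenitor over LN229 RNA of each gene list in the unamplified, 20 ng, 1 ng and 20 pg groups.

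Neighbouring input amounts were compared to see whether ratios changed from 20 ng to 1 ng and from 1 ng to 20 pg. FOSL1, an AP-1 transcription factor chosen after its values were seen, stood at -1.79 from 20 ng and -0.32 from 1 ng (difference 1.47 ± 0.19, SE, adjusted p = 0.00227), a call that ended in the earlier batch alone (1.58) and with the processed signals (1.47), and under several other alternatives. It was 1 of 7 genes (2 to 88 with each array left out) whose ratio differed between these groups, 5 upward and 2 downward, out of 1587 at an unadjusted p under 0.05. The count was 32 with the scan batch as a block, 48 in the earlier and 1241 in the later batch. From 1 ng to 20 pg limma called 1 gene (0 to 12 with each array left out), RAB11A, a GTPase of recycling endosomes on chromosome 15 that was chosen after its values were seen. Its log2 ratio was 0.59 in unamplified RNA, 0.50 from 20 ng, 0.53 from 1 ng and -1.91 ± 1.08 from 20 pg (SD, n = 6, higher in the progenitor RNA on 0 of 6 arrays), a difference of -2.45 ± 0.34 (SE, adjusted p = 0.00968). The RAB11A call ended without 1 ng replicate 3 (-2.37), without 20 pg replicate 2 (-2.22) or 3 (-2.29), and in either scan batch alone (-2.60 and -2.33), and under several other alternatives. The count was 5 with the batch as a block, 8 in the later batch and 0 by limma in the earlier batch, where 2932 genes had an unadjusted p under 0.05. Simulated recovery at 1.5 was 85% between 1 ng and 20 ng and 72% between 20 pg and 1 ng. Real differences that vary with the batch may be missed.

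From 20 ng to 1 ng camera called, but not with an estimated correlation, the histone (median difference 0.55), proliferation (0.80) and cancer-testis lists (0.34) upward and the fibroblast (-1.24) and mesenchymal lists (-0.42) downward, and fry called 0 of 25 lists. No member was called over all genes by limma, and adjusted over the list alone 0 cancer-testis, 4 histone, 5 proliferation, 5 fibroblast and 4 mesenchymal genes were, with 12, 24, 11, 7 and 9 at an unadjusted p under 0.05. Camera gave adjusted p = 1.12e-25 (histone), 9.95e-17 (proliferation), 9.54e-07 (cancer-testis and mesenchymal) and 2.45e-09 (fibroblast), and adjusted p = 0.288, 0.218, 0.244, 0.319 and 0.104 with an estimated correlation for histone, proliferation, cancer-testis, mesenchymal and fibroblast genes. None of the 5 was called in the earlier batch (adjusted p = 0.928, 0.354, 0.0879, 0.0879 and 0.473), where each pointed the other way. From 1 ng to 20 pg camera called, but again not with an estimated correlation, the respiratory chain (median -0.29), proteasome (-0.39), mesenchymal (-0.30) and metallothionein lists (-0.27) downward. It called the histone (0.35), proliferation (0.52) and cancer-testis lists (0.23) upward, where fry called 0 of 25. Their members called by limma numbered 0 over all genes and, adjusted over the list alone, 3 mesenchymal genes and 0 of the other 6 lists, with 9, 7, 3, 0, 5, 0 and 0 at an unadjusted p under 0.05 in that order. The adjusted p were 0.000140, 0.000268, 0.0142, 0.0266, 0.000222, 0.000559 and 0.0322, and 0.784 for histone and 0.719 for the other lists with an estimated correlation. The histone median was -0.29 in the earlier batch (adjusted p = 0.523). In the later batch the respiratory chain list had adjusted p = 0.815, the proteasome list 0.363, the proliferation list 0.161, the mesenchymal list 0.161, the metallothionein list 0.993 and the cancer-testis list 0.670.

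Across all tested genes the ratios of amplified RNA followed those of unamplified RNA less closely with less input, an order that depended on the settings. Pearson's r across genes, which are not independent replicates, was 0.818 for 20 ng, 0.747 for 1 ng and 0.440 for 20 pg, and Spearman's rho was 0.737, 0.633 and 0.306. The orthogonal slope on the unamplified ratios was 0.695, 0.437 and 0.274. With the slide as a fixed block rho was 0.678, 0.718 and 0.0288 and the slope 0.632, 0.694 and 0.409. Slides partly matched groups (slide 6 was all 20 pg), so this fit settles neither the order nor calls it ended. Among the 1282 genes of the strict filter rho was 0.791, 0.761 and 0.476 and the slope 0.839, 0.684 and 0.764. Without the later 1 ng and 20 pg arrays the slopes of both groups exceeded 1 at rho of 0.649 and 0.231. Simulated groups with no sample difference gave r of 0.165, 0.109 and 0.0577. With the scan batch as a block r was 0.840, 0.779 and 0.522. In the earlier batch r was 0.759, 0.786 and 0.421 with slopes of 0.740, 0.912 and 0.849, and in the later batch 0.828, 0.483 and 0.424 with slopes of 0.686, 0.176 and 0.189. The share of unamplified calls called the same way was 51.5%, 60.2% and 7.80% in the earlier and 48.2%, 6.76% and 8.85% in the later batch. In the earlier batch, without dye swaps, the 1 ng group thus had the highest r, slope and share of the 3. Differences between r values were not tested.

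**Figure D3:**
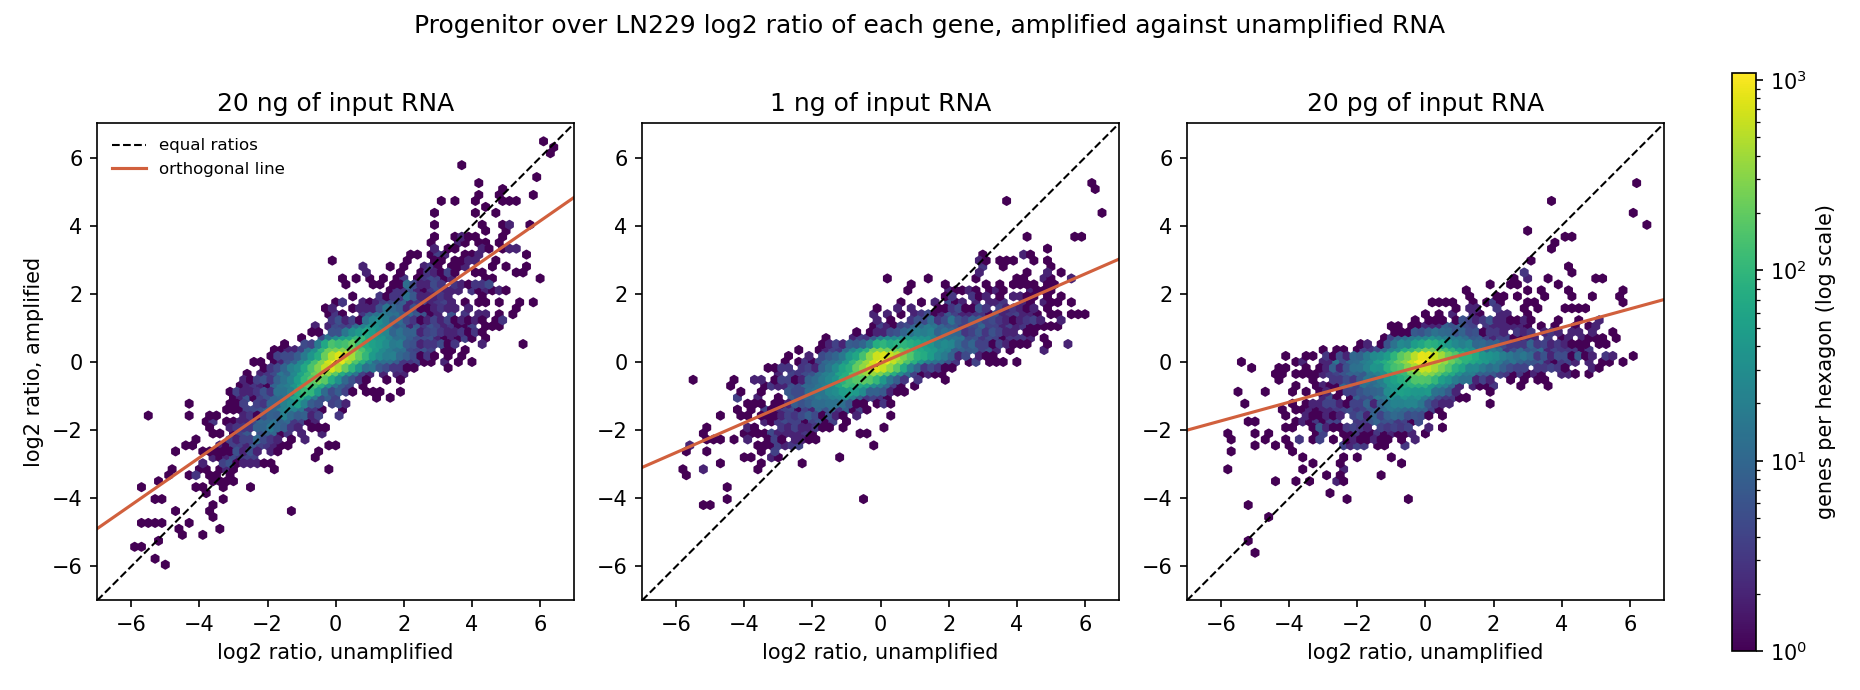
Log2 ratio of progenitor over LN229 RNA of each gene after amplification from 20 ng, 1 ng and 20 pg (y axis) against unamplified RNA (x axis), as hexagons coloured by the number of genes on a log scale, with the line of equal ratios and the orthogonal line.

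The spread between arrays of a group, over both scan batches, was larger at 1 ng and 20 pg than in unamplified RNA. The residual SD of the log2 ratio, over genes, was 0.239 for unamplified RNA, 0.262 for 20 ng, 0.372 for 1 ng and 0.493 for 20 pg. It was 0.0873, 0.143, 0.186 and 0.436 in the earlier and 0.209, 0.188, 0.235 and 0.283 in the later batch alone. The median absolute deviation of an array from its group averaged 0.209 ± 0.0271 (SD, n = 5), 0.219 ± 0.0270 (n = 5), 0.322 ± 0.0336 (n = 5) and 0.385 ± 0.0879 (n = 6). Two-sided exact permutation tests against unamplified RNA gave adjusted p = 0.556, 0.0119 and 0.00649 over 3 tests (0.533, 0.0250 and 0.0143 with exchanges within scan batches). All 1 ng and 20 pg deviations lay above every unamplified one. These were taken over both batches, so spread within batches was not tested. Pairs of unamplified arrays with the same dye orientation correlated at 0.974 in the earlier and 0.952 in the later batch, and pairs of opposite orientation at 0.802 and 0.807. For 20 ng the values in the same order were 0.940, 0.930, and 0.702 and 0.742. For 1 ng they were 0.879, 0.537, and 0.00325 and 0.100, and for 20 pg 0.406, 0.435 to 0.487, and -0.0405 to 0.0395.

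**Figure D4:**
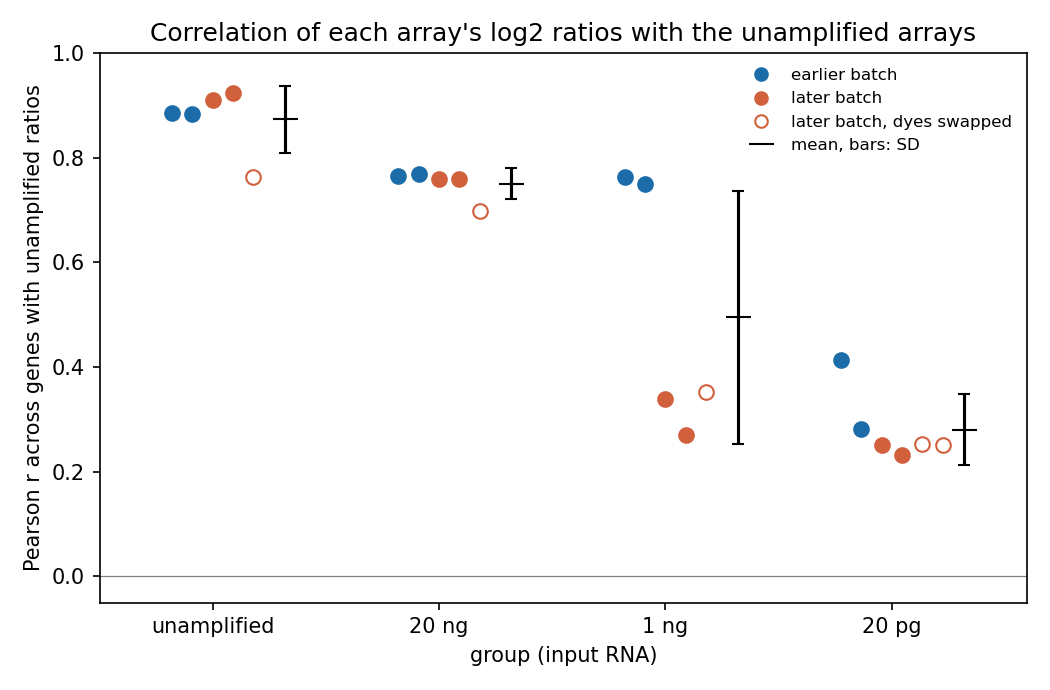
Pearson's r across genes of the oriented log2 ratios of each array with the mean of the unamplified arrays, by group, with dye orientation and scan batch marked.

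The differences of the 3 amplified groups from unamplified RNA shared genes. Of the genes that differed from 20 ng and from 1 ng, 276 rose and 503 fell in both, against 9.72 and 26.9 if the calls were independent, and CAPS (2.09 and 2.39), CADM3, ASCL2, CITED2 and PCDHA5 were among them. From 20 ng and 20 pg 262 rose and 542 fell in both (independent 14.9 and 49.2, 1 opposite), and from 1 ng and 20 pg 442 and 835 (independent 23.1 and 70.7). Because the unamplified arrays enter every difference, the differences correlate without any effect: simulated arrays gave r of 0.401, 0.347 and 0.269 with no shared call, against 0.855, 0.764 and 0.871 in the data. With the unamplified arrays split so that the differences shared none, r ranged over 20 splits from 0.424 to 0.840, from 0.427 to 0.774 and from 0.621 to 0.839.

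The average intensity of both dyes was compared between groups to see which transcripts became brighter or dimmer with amplification in both RNAs together. From 20 ng the anti-apoptotic gene BCL2A1 brightened from a log2 intensity of 7.93 (difference 5.06 ± 0.27, SE, adjusted p = 1.82e-11), the proteasome gene PSMB3 from 9.21 to 13.86 and ABRACL from 8.17 to 12.54. SRP14P1, CNPY2 and the chromatin gene DPY30 gained 4.17, 4.08 and 4.00. IL17RC, a receptor of interleukin 17, dimmed from 14.81 to 8.38 (difference -6.43 ± 0.32, SE, adjusted p = 1.7e-11), and TRIM7, the transporter SLC22A7, OR6W1P and the mannosidase MAN1B1 by -5.01, -4.89, -4.43 and -4.27. From 1 ng BCL2A1 gained 5.42, the factor BCL11A 5.07, TMEFF2 5.06, ABRACL 5.04, SEMA6B 5.00 and the integrin ITGAE 4.95. IL17RC changed by -5.74, LRFN1 by -4.61, MAN2A2 by -4.49, MAN1B1 by -4.26 and LGR4 by -4.23. The MAN2A2 call ended as the mean of its probes. From 20 pg ABRACL rose from 8.17 to 13.77 (difference 5.60 ± 0.24, SE, adjusted p = 9.04e-13), ITGAE by 5.29, DPY30 by 5.27, TMEFF2 by 5.23, COA6 by 5.15 and BCL2A1 by 5.06. The actin crosslinker FLNA dimmed from 12.45 to 7.79 (difference -4.66 ± 0.32, SE, adjusted p = 8.26e-10), IL17RC from 14.81 to 8.62, and SLC22A7, MAN1B1, NBPF9 and LRFN1 by -4.90, -4.89, -4.84 and -4.72. SLC22A7 lost its 20 pg call as the mean of its probes.

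The average intensity differed from unamplified RNA for 4791 genes from 20 ng (2928 brighter and 1863 dimmer), 5827 from 1 ng (3124 and 2703) and 7880 from 20 pg (3927 and 3953). With the scan batch as a block the counts were 4975, 6179 and 8245, with 6453, 5974 and 8602 in the earlier and 4931, 7218 and 9053 in the later batch. The split into brighter and dimmer rested on quantile normalization: with median centring of the intensities 2928 genes were brighter and 3917 dimmer from 20 ng, 1966 and 4779 from 1 ng and 2756 and 7262 from 20 pg. Simulated recovery at 1.5 was 85%, 58% and 69%.

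Of 77 transcripts of the respiratory chain encoded in the nucleus, 54 were called brighter from 20 ng and 2 dimmer (median 1.49), with UQCR11 at 3.00 and COX7A2 at 2.88. From 1 ng the numbers were 40 and 3 (42 and 4 adjusted over the list alone, median 1.04), and from 20 pg, 31 and 10 (median 0.70), although the 20 pg median relative to all genes turned to -0.549 with median centring. Of 64 replication-dependent histone transcripts, most of which lack poly(A) tails, 32 were called dimmer and 3 brighter from 1 ng (37 and 3 adjusted over the list alone, median -1.17), and from 20 pg, 53 dimmer and 1 brighter (median -2.57). H4C15 dimmed from 12.96 in unamplified RNA to 8.60 from 20 pg, and H2AC6 and H2BC11 by -4.09 and -3.98. Of 20 proliferation genes 7 were called dimmer from 1 ng and 11 from 20 pg, with TOP2A at -2.24, and of 6 transcripts of the mitochondrial genome 4 and 5, with COX1 at -3.42 from 20 pg. From 20 ng proteasome genes were called brighter for 16 and dimmer for 1 of 37, with PSMD2 at 2.65, metallothionein genes for 8 and 1 of 11, with MT2A at 1.35, and ribosomal protein genes for 16 and 2 of 84, with RPL22 at 2.83. From 1 ng astroglial genes were called brighter for 5 and dimmer for 1 of 10, with GJA1 at 3.47.

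In these intensity tests camera gave the respiratory chain list adjusted p = 4.44e-28 from 20 ng, 1.05e-10 from 1 ng and 0.000212 from 20 pg, and 0.00964, 0.173 and 0.467 with an estimated correlation. The histone list had adjusted p = 4.93e-09 from 1 ng and 7.53e-29 from 20 pg, and 0.173 and 0.0189 with an estimated correlation. For proliferation genes the adjusted p was 0.0357 from 1 ng and 0.0106 from 20 pg (0.609 and 0.478 with an estimated correlation), and for the mitochondrial genome 0.0443 and 0.0106 (0.375 and 0.330 with an estimated correlation), where the 1 ng call ended with the scan batch as a block (adjusted p = 0.118). From 20 ng metallothionein and proteasome genes had adjusted p = 9.6e-06 (0.157 with an estimated correlation) and ribosomal protein genes 0.000246 (0.332 with an estimated correlation), and from 1 ng astroglial genes 0.0443 (0.228 with an estimated correlation). In the earlier batch the proliferation call ended from 1 ng (adjusted p = 0.458) and 20 pg (0.135), the mitochondrial genome call from 1 ng (0.295), the respiratory chain call from 20 pg (0.0639) and the astroglial call from 1 ng (0.252, and 0.0621 in the later batch).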

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

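The tests of the dye bias, of arrays that were not swapped, of exchanged names and of fibroblasts, all splits of the arrays, and for dim spots the strict filter and the condition that most of the brightest genes be above background were chosen after the results they concern had been seen. The correlation across genes of an array's ratios with the unamplified mean stood apart for 3 arrays: unamplified replicate 5 at 0.763 (others 0.884 to 0.924), 20 ng replicate 5 at 0.698 (others 0.758 to 0.770) and 20 pg replicate 1 at 0.414 (others 0.232 to 0.281). The first 2 are the dye-swapped arrays of their groups and the last is an earlier-batch array, so dye orientation and batch go with these flags. The share of outlier spots on 20 pg replicate 1 was 0.397% (others 0.666 to 0.828%). Chance alone sets apart about 1 in 20 groups, or 1.6 of the 32 tested, against 4 here. A control probe for a viral spike-in, which no comparison used, was 1.91 log2 units brighter over its local background at 1 ng than in unamplified RNA (8.47 and 10.4, two-sided exact p = 0.00794, adjusted p = 0.0437 over 33 tests and 0.0458 within scan batches). The same probe differed by 2.04 at 20 ng (exact adjusted p = 0.0952) and 0.697 at 20 pg (0.254), and other such probes moved either way, -1.28 and -1.45 at 20 ng and 1.63 at 1 ng among them (adjusted p = 0.0437 each).

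Ratios differed between groups for 1014 genes from 20 ng and unamplified RNA, 1502 from 1 ng and 2569 from 20 pg. Of 100 splits of the arrays only the real one gave as many (highest others 315, 695 and 309). This argues against chance between arrays, not between amplifications. Between 1 ng and 20 ng 7 genes differed and 8 of 100 splits gave as many (highest other 741), so chance cannot be excluded. The highest follows the scan batch, and 1241 genes differed in the later batch alone. With exchanges within batches only 4 of 60 splits gave as many (highest other 129), and with the batch as a block 4 gave as many as the real 32 (highest other 507). Between 20 pg and 1 ng 1 gene differed and 12 of 100 splits gave as many (highest other 105), so chance cannot be excluded here either. The highest again follows the scan batch, and within batches the numbers were 9 of 100 (429), and 3 for the 5 genes with the batch as a block (255). Splits with many more genes than the real one point to a structure of the arrays other than their groups. For average intensity only the real split gave 4791, 5827 and 7880 genes in 100 splits each (highest others 2085, 53 and 5640). The same limit holds. At 20 pg the 584 genes with a ratio off 1 exceeded every other way to turn the array signs (highest other 307). A share of 1 in 32 cannot exclude chance. For 3413 genes in unamplified RNA (highest other 76), 1894 from 20 ng (highest other 26) and 568 from 1 ng (highest other 430) the 16 ways are too few for a share under 0.05.

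Log2 ratios lay nearer 0 after amplification, most on later 1 ng and 20 pg arrays (mean slopes 0.157 and 0.157, earlier 0.841 and 0.435). Background under dim spots is a candidate explanation. Among the 7351 brightest genes the slope on the unamplified ratios was 0.832 at 20 ng (with each array left out 0.814 to 0.846), 0.546 at 1 ng (0.448 to 0.646) and 0.457 at 20 pg (0.409 to 0.531), against 0.427, 0.279 and 0.0619 among as many of the dimmest. Their shortfall of the slope from 1 was 0.552 at 20 ng, 0.806 at 1 ng and 0.748 at 20 pg of that over all genes, which met the bound set beforehand against dim spots at 1 ng alone, but only 21.6% of them were well above background in both channels on all arrays there (83.3% at 20 ng and 28.4% at 20 pg), so the test decides nothing. With the strict filter the slopes were 0.839, 0.684 and 0.764 and the shares 0.527, 0.562 and 0.324, and the explanation stays open in all 3 groups. An offset of 1 gave a highest slope of 0.796, which argues against the offset as the whole cause, and a loss of transcripts in amplification itself was not tested.

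Forward and dye-swapped arrays disagreed among the later 1 ng and 20 pg arrays, and a dye bias of each probe is a candidate explanation. The part of the ratio that keeps its sign when dyes are exchanged correlated between the 1 ng and 20 pg arrays at 0.638 across genes (0.544 to 0.656 with each array left out), which is consistent with it. The SD of the dye part across genes was 0.301 at 1 ng and 0.359 at 20 pg, close to that of the sample part (0.314 and 0.356), against 0.295 and 0.911 in unamplified RNA. The lowest correlation of a swapped array's oriented ratios with the unamplified ones was 0.251, which argues against arrays that were not swapped. Probe GC content stays open, since its correlation with the 20 pg dye part was -0.124 (-0.136 to -0.0912 with each array left out). It was 0.279 with the dye part of unamplified RNA. No biological explanation was tested.

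Fibroblast genes were higher in the progenitor RNA, and SOX10, S100B and MIA in the LN229 RNA. Exchanged names of the RNAs are argued against by CDKN2A, which LN229 is known to have lost and which had a log2 ratio of 4.39 on average, higher in the progenitor RNA on 5 of 5 arrays. Fibroblast or mural cells among the progenitor cells stay open, since the 10 of 12 markers called higher restate the pattern and decide nothing, with log2 levels in the progenitor RNA of 13.8 for COL1A2, 13.4 for TAGLN and 12.6 for COL3A1, and the mesenchymal and collagen lists hold some of the same genes. Melanocytic cells or genes in the LN229 RNA are argued against by pigment cell markers, of which 1 of 5 tested was called higher in LN229 (MITF at -1.43). A true difference between the cells stays open and was not tested.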

How the results depend on the processing

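Alternatives named in the methods as added, both batches alone among them, were chosen after seeing the data. Over all alternatives 813 values of group results lay within the spread or within 1.5 times the count, and 173 did not. Of the values of named genes 7114 kept direction and stayed on the same side of the threshold, 171 kept the direction without the call, 10 gained a call and 24 turned, of which only those of H2AJ had been called. Apart from single arrays left out these were SOX2 (1 ng minus unamplified) at -0.23 with the processed signals, -0.12 with an offset of 1, -0.0283 with the slide as a fixed block, -0.12 with the series matrix values, -0.78 in the earlier batch alone and -0.95 without the later 1 ng and 20 pg arrays; GAPDH (unamplified) at 0.24 with median centring, 0.0520 without the dye-swapped arrays, 0.11 with a replicate block in place of the dye term and 0.20 in the earlier batch alone; FN1 (20 ng minus unamplified) at -0.30 with median centring, -0.000304 with the mean of probes, -0.27 with the slide as a fixed block and -0.15 in the later batch alone; FN1 (20 pg minus unamplified) at 0.45 with scale normalization; MYC (unamplified) at 0.20 without the dye-swapped arrays, 0.78 with the mean of probes, 0.15 with the slide as a fixed block and 0.41 in the earlier batch alone; H2AJ (1 ng minus unamplified) at -0.55 with the mean of probes; H2AJ (20 pg minus unamplified) at -0.69 with the mean of probes; FN1 (1 ng minus unamplified) at 0.00865 in the earlier batch alone. Of 80 list calls 76 held with the scan batch as a block, 52 in the earlier batch alone (11 pointed the other way) and 65 in the later (2 the other way). The number was 63 with the processed signals, 79 without the filter and 62 of the 67 tested with median centring. An estimated correlation kept 6 and fry 62 (6 lists called with the estimated correlation and 121 lists called with fry). Replicate numbers did not pair the arrays, since only 18 of 30 same-number pairs correlated above 0.1 and the best match had the same number for 10, so the pairing was used only as an alternative block. The cause was not tested for any of the following values, except that the strict filter and the smaller fits use fewer genes or arrays.

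With the processed signals, genes with a ratio off 1 numbered 5719 (unamplified), 4424 (20 ng), 1359 (1 ng, with 374 higher and 985 lower) and 973 (20 pg). The ratio differed for 1523 (20 ng minus unamplified), 196 (1 ng minus 20 ng, with 88 higher and 108 lower) and 5 (20 pg minus 1 ng) genes. The intensity differed for 9311 (20 ng minus unamplified, with 4706 higher and 4605 lower) genes. The share called the same way was 56.8% (20 ng). The SD between arrays was 0.363 (unamplified), 0.531 (20 ng), 0.672 (1 ng) and 1.02 (20 pg). With an offset of 1, genes with a ratio off 1 numbered 3024 (20 ng) and 1174 (1 ng). Genes whose ratio differed numbered 1126 (20 pg minus unamplified), 0 (1 ng minus 20 ng) and 3 (20 pg minus 1 ng, with 1 higher and 2 lower). Called the same way were 57.2% (20 ng). The SD was 0.278 (unamplified), 0.383 (20 ng), 0.619 (1 ng) and 0.945 (20 pg). With median centring in place of loess, genes whose ratio differed numbered 0 (20 pg minus 1 ng). The SD was 0.287 (unamplified), 0.368 (20 ng), 0.409 (1 ng) and 0.634 (20 pg). With scale normalization, genes whose ratio differed numbered 634 (20 ng minus unamplified), 356 (1 ng minus 20 ng, with 176 higher and 180 lower) and 2 (20 pg minus 1 ng). The share called the same way was 57.4% (20 ng). Without the filter, the SD was 0.332 (1 ng). With the strict filter, which left fewer genes, genes with a ratio off 1 numbered 153 (unamplified), 102 (20 ng), 73 (1 ng) and 99 (20 pg, with 30 higher and 69 lower). In ratio, 33 (20 ng minus unamplified, with 8 higher and 25 lower), 43 (1 ng minus unamplified, with 9 higher and 34 lower), 11 (20 pg minus unamplified, with 0 higher and 11 lower), 2 (1 ng minus 20 ng, with 0 higher and 2 lower) and 0 (20 pg minus 1 ng) genes differed. Genes whose intensity differed numbered 539 (20 ng minus unamplified, with 400 higher and 139 lower), 591 (1 ng minus unamplified, with 476 higher and 115 lower) and 677 (20 pg minus unamplified, with 474 higher and 203 lower). The correlation was 0.568 (20 pg). Called the same way were 56.2% (20 ng) and 32.7% (20 pg). The SD was 0.195 (unamplified), 0.189 (20 ng), 0.232 (1 ng) and 0.666 (20 pg). Without a dye term, the SD was 0.286 (unamplified). Without the dye-swapped arrays, genes with a ratio off 1 numbered 1549 (1 ng). Ratio differences were called for 0 (1 ng minus 20 ng) and 0 (20 pg minus 1 ng) genes. The SD was 0.211 (unamplified). With equal array weights, genes whose ratio differed numbered 5 (20 pg minus 1 ng). With a replicate block in place of the dye term, genes whose ratio differed numbered 3 (1 ng minus 20 ng, with 3 higher and 0 lower). The SD was 0.286 (unamplified). With the mean of a gene's probes, genes whose ratio differed numbered 0 (20 pg minus 1 ng). Without a fold minimum, genes with a ratio off 1 numbered 10974 (unamplified), 6947 (20 ng) and 983 (1 ng). The ratio differed for 3065 (20 ng minus unamplified), 2896 (1 ng minus unamplified) and 4071 (20 pg minus unamplified) genes. The intensity differed for 10091 (20 ng minus unamplified, with 5032 higher and 5059 lower) genes. With the scan batch as a block, genes with a ratio off 1 numbered 1111 (1 ng) and 891 (20 pg). Genes whose ratio differed numbered 32 (1 ng minus 20 ng, with 16 higher and 16 lower) and 5 (20 pg minus 1 ng). The correlation was 0.522 (20 pg). With the slide as a fixed block, genes with a ratio off 1 numbered 1125 (1 ng) and 1446 (20 pg). In ratio, 382 (20 ng minus unamplified), 1118 (20 pg minus unamplified, with 249 higher and 869 lower), 3 (1 ng minus 20 ng, with 0 higher and 3 lower) and 2 (20 pg minus 1 ng) genes differed. The correlation was 0.782 (20 ng) and 0.187 (20 pg), the share called the same way 38.9% (20 ng) and the SD 0.288 (unamplified). With the slide as a random block, genes whose ratio differed numbered 0 (1 ng minus 20 ng) and 0 (20 pg minus 1 ng). The SD was 0.271 (unamplified). With the submitters' series matrix values, genes with a ratio off 1 numbered 5765 (unamplified), 4497 (20 ng), 1258 (1 ng) and 900 (20 pg). Ratio differences were called for 1749 (20 ng minus unamplified, with 863 higher and 886 lower), 259 (1 ng minus 20 ng, with 140 higher and 119 lower) and 3 (20 pg minus 1 ng) genes. Called the same way were 57.5% (20 ng). The SD was 0.349 (unamplified), 0.485 (20 ng), 0.668 (1 ng) and 1.02 (20 pg). With a dye term per group, genes with a ratio off 1 numbered 227 (1 ng). The ratio differed for 0 (20 pg minus 1 ng) genes. The SD was 0.182 (unamplified), 0.218 (20 ng) and 0.316 (1 ng). With a dye term per group and the batch block, genes whose ratio differed numbered 40 (1 ng minus 20 ng) and 0 (20 pg minus 1 ng). The correlation was 0.532 (20 pg) and the SD 0.195 (unamplified), 0.229 (20 ng) and 0.325 (1 ng). In the earlier batch alone, genes with a ratio off 1 numbered 3793 (20 ng) and 4916 (1 ng). Genes whose ratio differed numbered 1981 (20 ng minus unamplified), 535 (20 pg minus unamplified, with 28 higher and 507 lower), 48 (1 ng minus 20 ng) and 0 (20 pg minus 1 ng). The correlation was 0.759 (20 ng) and the share called the same way 60.2% (1 ng). The SD was 0.0873 (unamplified), 0.143 (20 ng) and 0.186 (1 ng). Probes detected were 79.3% (unamplified), 77.3% (1 ng) and 71.0% (20 pg). In the later batch alone, genes with a ratio off 1 numbered 275 (1 ng, with 76 higher and 199 lower). In ratio, 2891 (1 ng minus unamplified), 1241 (1 ng minus 20 ng, with 610 higher and 631 lower) and 8 (20 pg minus 1 ng, with 5 higher and 3 lower) genes differed. Ratios correlated at 0.483 (1 ng). The SD was 0.209 (unamplified), 0.188 (20 ng), 0.235 (1 ng) and 0.283 (20 pg). Without the later 1 ng and 20 pg arrays, genes with a ratio off 1 numbered 3648 (1 ng). Ratio differences were called for 652 (20 pg minus unamplified, with 86 higher and 566 lower), 325 (1 ng minus 20 ng, with 136 higher and 189 lower) and 149 (20 pg minus 1 ng, with 29 higher and 120 lower) genes. The correlation was 0.349 (20 pg), the share called the same way 58.5% (1 ng) and the SD 0.186 (1 ng). With only the groups compared, genes with a ratio off 1 numbered 42 (1 ng, with 9 higher and 33 lower) and 61 (20 pg, with 27 higher and 34 lower). The ratio differed for 2 (1 ng minus 20 ng, with 2 higher and 0 lower) and 0 (20 pg minus 1 ng) genes. The SD was 0.182 (unamplified), 0.218 (20 ng) and 0.316 (1 ng). With the flag for positive and significant signal, probes detected were 83.6% (unamplified) and 67.2% (20 ng).

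With each array left out in turn genes with a ratio off 1 ranged from 285 to 955 (1 ng). Genes whose ratio differed ranged from 2 to 88 (1 ng minus 20 ng) and 0 to 12 (20 pg minus 1 ng). The correlation ranged from 0.786 to 0.831 (20 ng). The SD ranged from 0.211 to 0.251 (unamplified) and 0.393 to 0.510 (20 pg). The log2 value ranged from -0.136 to 0.0167 for GAPDH (unamplified) and -0.0825 to 0.123 for FN1 (20 ng minus unamplified).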

Other observations

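Of the tests in this part those of named genes and of the HOX list were planned in advance, and HOXB3, HOXB5, HOXB6, HOXB7, HOXC4 and HOXC6 were chosen after their values were seen. Members of the HOX list, which pattern the body axis, went both ways in unamplified RNA (list adjusted p = 0.129). HOXB2, HOXB3, HOXB4, HOXB5 and HOXB6 were higher in the progenitor RNA, at log2 ratios of 3.42, 1.98, 2.41, 2.27 and 1.21, each on 5 of 5 arrays (highest adjusted p = 1.82e-05). HOXB7 of the same cluster was lower at -1.55, as were HOXC4 at -1.43, HOXC6 at -1.48 and HOXC10 at -2.44 (highest adjusted p = 7.75e-07, lower on 5 of 5 arrays). HOXB6 fell short of the 2-fold minimum in the earlier batch alone (0.93), with the mean of its probes (0.98) and with the slide as a fixed block (0.87).

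Of the genes chosen beforehand, CDKN2A and EGFR had ratio differences that were called after amplification. FN1 stood at 2.64 in unamplified RNA, 2.69 from 20 ng, 2.12 from 1 ng and 2.36 from 20 pg, with differences from unamplified RNA of 0.05, -0.52 and -0.28 (adjusted p = 0.919, 0.130 and 0.492). SOX2 stood at -2.07, -1.90, -1.59 and -1.89 (adjusted p of the differences 0.862, 0.599 and 0.865). The 20 pg difference of FN1 was -1.39 and called with the mean of its probes, and the 1 ng difference of SOX2 was 1.31 and called in the later batch alone. CDKN2A fell from 4.39 to 2.27, 1.16 and 0.88 (differences -2.12 ± 0.39, -3.23 ± 0.48 and -3.51 ± 0.55, SE, adjusted p = 0.000751, 0.000102 and 0.000178), with the 20 ng call ending with the slide as a fixed block (-2.81) and the others in the earlier batch alone (-1.03 and -3.34). The EGFR differences from 1 ng (-1.28) and 20 pg (-1.29) were called as well (adjusted p = 0.000119 and 0.000423), and ended in the earlier batch alone (-0.78 and -0.59). For each of FN1 and SOX2 a missed threshold does not show that the ratios did not differ.

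Of 6026 genes with several probes, 522 had probes at least 1 log2 unit apart and 15 had probes of opposite sign, both beyond 1.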
